A study of Homo sapiens with 4 samples.

How the data were processed

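RNA was measured in 4 extracts of MIA PaCa-2, an established human pancreatic cancer cell line, on Affymetrix Human Genome U133 Plus 2.0 arrays. Each array reads a transcript through 1 or more probe sets, which are groups of short probes that mostly lie near the 3' end of the transcript. Per the labels, 2 RNA extracts came from cells stably transfected with an empty vector and 2 from cells stably transfected with an NDRG1 vector. The labels do not say whether the 2 extracts of a group came from separate cultures. The p-values therefore rest on the spread between these extracts, pooled largely across probe sets, and that spread may be technical.

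The deposited values are MAS5 intensities on a linear scale, with MAS5 named in the submitters' processing notes and no version given there. The scaling target of each array is not given in the sources used here. The deposited intensity table holds 54675 probe sets, 62 of them control probe sets of the array maker, and 5 values are listed at 0. The files show that the arrays fall into 2 batches that coincide with the replicate number. In both replicate 1 arrays 100% of values have at most 1 decimal, against 1.02% and 1.19% in the replicate 2 arrays. The trimmed mean, leaving out 2% at each end, was 175 in control 1 and 111 in the array labelled NDRG1 of replicate 1, and 150.021 in both replicate 2 arrays. The replicate 2 arrays were thus at a common trimmed mean, and the replicate 1 arrays were not. The replicate 1 arrays did not differ by a single factor. Their median signal was 38.2 and 33.3, control first, and their highest signal 15056.9 and 12886.1. The difference between them thus varied with intensity, and its cause was not tested. Each batch holds 1 array of each group, so values are given within each replicate pair and with the replicate number as a block. Detection calls were not used here, and the number of arrays limits the precision.

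Probe sets were named through the platform annotation. Of the probe sets outside the controls, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none. The gene identifier of 41043 of those with 1 symbol matched the RefSeq gene table, and 0 symbols changed. Probe sets with several symbols or none were tested and left unnamed.

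Intensities were analysed as log2(value + 8.9), where 8.9 is the 25th percentile of all values, so a fold change on this scale understates the change of dim genes. No further normalization between arrays was applied in the main analysis. Probe sets with a mean log2 value above the median of all probe sets were kept, which left 27306. The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, group as the only term, and Benjamini-Hochberg adjustment over all tested probe sets with a threshold of 0.05. This fit draws each probe set's spread toward a spread shared by all, here with 33.3 prior against 2 residual degrees of freedom. The SE of a called gene, 0.45 to 0.52, is thus mostly shared and not that gene's own spread between extracts. A gene was represented by its kept probe set with the highest mean over the 4 arrays, which gave 12115 genes. The median log2 difference over tested probe sets was -0.30, and changes are reported relative to this median unless another scale is named. This takes off a constant only, so a difference between arrays that varies with intensity stays. Ribosomal protein genes, for example, had a median of 0.23 relative to all genes, and of 0.005 after quantile normalization. The p-values of single probe sets test the fitted difference before the median of -0.30 is taken off, which favours calls of lower genes.

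A total of 45 gene lists was drawn up from general knowledge of pancreatic cancer lines and transfection. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 41 lists that had at least 5 tested genes. The correlation was also estimated from the residuals of each list. The individual values of some tested lists that did not pass are not reported here. Named genes were NDRG1 and, in each direction, up to 12 genes with adjusted p under 0.05 and no overlap between the groups, ordered by the size of the log2 difference. For a list that passed, up to 4 members with the smallest p are named, and for another list at most 2. The groups, the test, the gene lists, the naming rule and most alternative settings were fixed before the data were examined. The alternatives were other pseudocounts, filters, normalizations between arrays, variance models, rules for choosing a probe set, the replicate block, and leaving out each array. Scaling to a common trimmed mean, the replicate block together with quantile normalization, and counts within a pair were added after the data were seen.

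The procedure was tested on simulated data with the means of the 27306 tested probe sets and the spread that limma estimated for them. The simulated noise was independent between probe sets and arrays, without batches or unequal scaling. The rates that follow hold for such data and may not hold for these arrays. Of probe sets changed by a log2 step of 1, 4% were recovered, against 76% at a step of 2 and 100% at steps of 3 and 4, with 5 false calls. With 2 arrays per group, an exact permutation test of a single gene cannot give a p below 0.333.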

Results

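NDRG1 encodes a cytoplasmic protein that responds to hypoxia, iron depletion and differentiation, and the series compared pancreatic cancer cells carrying an NDRG1 vector with cells carrying an empty vector. Expression was measured in MIA PaCa-2 cells on 4 arrays, 2 per group. The question addressed by the design is which transcripts differ between cells of the 2 transfections.

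The 2 control arrays resembled each other more closely than the 2 arrays labelled NDRG1 transfected. Across tested probe sets the Pearson correlation was 0.965 between controls and 0.901 between the arrays labelled NDRG1 transfected. After quantile normalization the SD of the log2 difference was 0.457 between controls and 0.808 between the arrays labelled NDRG1 transfected, against 0.595 and 0.572 within replicate pairs 1 and 2. The ratio of the 3' to the 5' control probe set, which rises when RNA is degraded, was 0.978 and 1.01 for GAPDH in the controls and 0.967 and 1.10 in the arrays labelled NDRG1 transfected. For ACTB it was 1.13 and 1.20 in the controls and 1.07 and 1.18 in the other arrays. The 5' probe set for 18S ribosomal RNA separated the replicates, at 80.9 and 63.9 in replicate 1 and 2259 and 554 in replicate 2, in each case the control first.

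The NDRG1 transcript was not higher in the arrays labelled NDRG1 transfected. Its only probe set read 349.8 and 152.003 in the controls and 99.8 and 141.895 in the arrays labelled NDRG1 transfected. The difference relative to the median of tested probe sets was -0.61 on the log2 scale (SE 0.47, n = 2 per group). With an adjusted p of 0.865 it did not pass the threshold. After quantile normalization it was -1.15 in pair 1 and -0.09 in pair 2, and the adjusted p with the replicate block was 0.825. The position of the probes on the transcript is not known here, and a transgene without the native 3' end would not be read by probes placed there. The value therefore goes against the label without testing it, and the arrays are named by their label throughout.

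Among the 12115 genes, 17 passed the threshold in the main fit, 9 of them higher and 8 lower in the arrays labelled NDRG1 transfected. With quantile, cyclic loess or trimmed-mean scaling between arrays, 0 genes passed without the replicate block. The largest increase was in LRRN3, a leucine-rich repeat membrane protein of neurons, which rose by 4.87 on the log2 scale relative to the median. FABP5, an intracellular carrier of fatty acids, rose by 3.75, and SAMSN1, an adaptor protein known from blood cells, by 3.58. DIO2, the deiodinase that activates thyroid hormone, rose by 3.19, and NEDD4L, a ubiquitin ligase that directs membrane proteins to degradation, by 2.96. The largest decrease was in TUBB2B, a beta-tubulin, followed by APOBEC3G, a cytidine deaminase that restricts viruses, and ALDH1A3, which makes retinoic acid. The order of TUBB2B and APOBEC3G turned without a pseudocount, with cyclic loess normalization, and without control 1 or the first array labelled NDRG1 transfected.

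LRRN3 signal was 43.9 and 29.7844 in the controls and 604.4 and 1876.56 in the arrays labelled NDRG1 transfected. Its log2 difference relative to the median was 4.87 (SE 0.49), with an adjusted p of 5.78e-07, and the fitted difference of 4.57 was 3.76 without the second array labelled NDRG1 transfected and 5.38 without the first. The control signals of LRRN3, FABP5, SAMSN1, DIO2, FSTL5, DSEL and GRID1 lie near or below the median signal of the arrays, 29.1 to 38.2, so the sizes of their changes depend on the pseudocount and are approximate. The fitted difference of SAMSN1 ranged from 2.24 with the median as pseudocount to 4.64 without any. FABP5 was 3.75 higher (SE 0.47, adjusted p = 0.000145) and SAMSN1 3.58 higher (SE 0.52, adjusted p = 0.00112), although 1 control array reads SAMSN1 at 2.1. DIO2 was 3.19 higher, with an adjusted p of 0.00233, and 2 further DIO2 probe sets were also called, while the fitted difference of 2.89 was 1.97 over the mean of its 4 kept probe sets (adjusted p = 0.00965). The remaining genes that rose were FSTL5, a follistatin-like secreted protein, by 3.04, NEDD4L by 2.96, DSEL, related to dermatan sulfate epimerase, by 2.89, COL3A1, a fibrillar collagen chain, by 2.77, and GRID1, a glutamate receptor subunit, by 2.49. Their adjusted p ranged from 0.00691 for DSEL to 0.0482 for GRID1. The kept probe sets of GRID1 and NEDD4L did not all move: over their mean the fitted log2 difference was 1.19 for GRID1 (adjusted p = 0.459) and 1.55 for NEDD4L, of whose 6 probe sets 2 were called (adjusted p = 0.116). The other GRID1 probe set read 0.19 (adjusted p = 0.939). Further kept probe sets of 3 of these genes rose without being called. Their fitted differences were 2.11 for SAMSN1 (adjusted p = 0.103), 1.73 for DSEL (adjusted p = 0.517), and 2.07 and 2.14 for COL3A1 (adjusted p = 0.0753 and 0.156). COL3A1 differed most between the pairs, at 4.39 in pair 1 and 1.31 in pair 2 after quantile normalization.

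Relative to the median, TUBB2B fell by 2.87 (SE 0.48, adjusted p = 0.000576), from 931.3 and 1805.97 in the controls to 92.3 and 199.573. Its probe set is of a class that may also read other tubulin transcripts. APOBEC3G fell by 2.80 (SE 0.48, adjusted p = 0.000769) and ALDH1A3 fell by 2.47 (SE 0.52, adjusted p = 0.0122). PMAIP1, which encodes the pro-apoptotic protein NOXA, fell by 2.13, and CLDN11, a tight-junction claudin, fell by 2.10. PRAG1, a pseudokinase, fell by 2.09, the lysosomal protease CTSC fell by 2.01, and the long noncoding RNA LINC00467 fell by 1.86. Their adjusted p ranged from 0.0161 for CLDN11 to 0.0376 for PMAIP1, PRAG1 and LINC00467. The p-values of the lower genes belong to larger fitted differences, such as -2.15 in place of -1.86 for LINC00467. Without the first array labelled NDRG1 transfected the fitted difference of PRAG1 was -1.46 in place of -2.38 (adjusted p = 0.0654), and that of PMAIP1 was -1.59 in place of -2.42 (adjusted p = 0.00999). With probe sets unique to a gene preferred, CTSC was represented by another probe set, with an adjusted p of 0.0747. A dimmer CTSC probe set of the same class was called, at a fitted -2.18 (adjusted p = 0.0314). The other kept LINC00467 probe set was at a fitted -1.67 and not called (adjusted p = 0.244). Over the mean of its kept probe sets CLDN11 was at -1.68 in place of -2.39 (adjusted p = 0.0328). No further probe set of a named gene was called in the opposite direction.

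**Figure D1:**
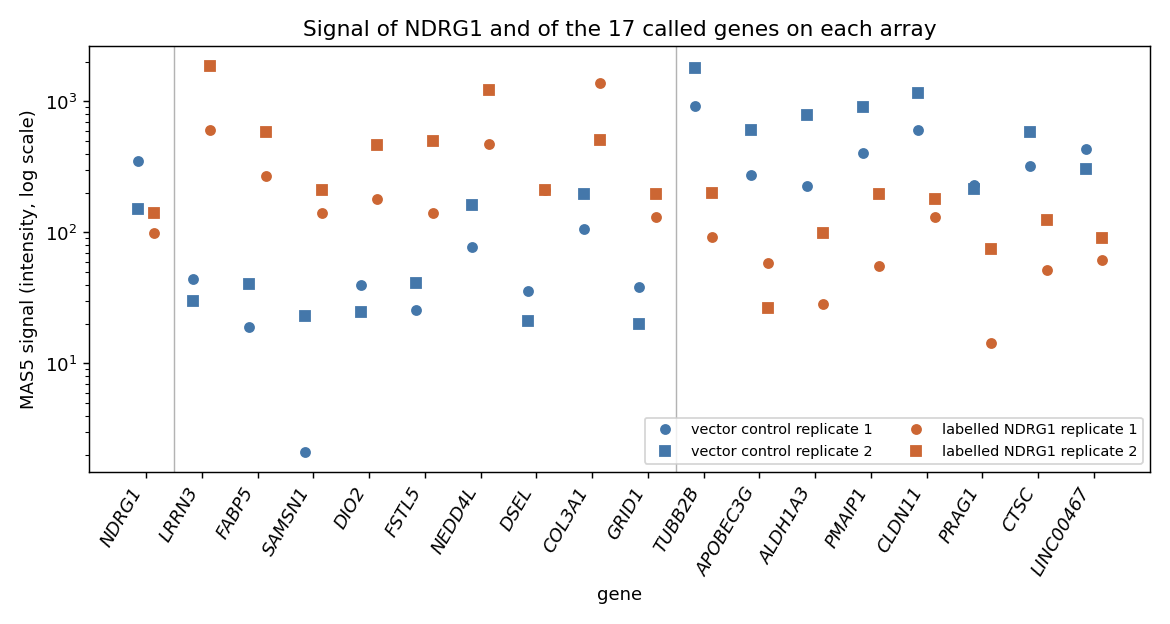
MAS5 signal (intensity, log scale) of NDRG1 and of the 17 called genes on each of the 4 arrays, with circles for replicate 1 and squares for replicate 2. The 9 genes after NDRG1 lie higher and the last 8 lower in both arrays labelled NDRG1 transfected than in both controls.

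By limma, 27 of 27306 probe sets passed an adjusted p of 0.05, 14 higher and 13 lower, and 1549 had an unadjusted p under 0.05. All 27 differed at least 2-fold in the same direction in both replicate pairs after quantile normalization. They were selected on these same arrays, which favours such agreement, so it is not separate evidence. With the replicate number as a block, 99 probe sets were called, 33 higher and 66 lower, and these included all 27. The calls depended on the scaling, as quantile normalization without the block left 0 (lowest adjusted p 0.322, 909 at an unadjusted p under 0.05). The block together with quantile normalization called 40, of which 23 were among the 27 and in the same direction; COL3A1 and PRAG1 were then at adjusted p = 0.0654 and 0.0730. Of the 17 genes, 15 lost the call without control 1 and 14 without control 2, when the spread came from the more divergent pair of arrays alone.

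**Figure D2:**
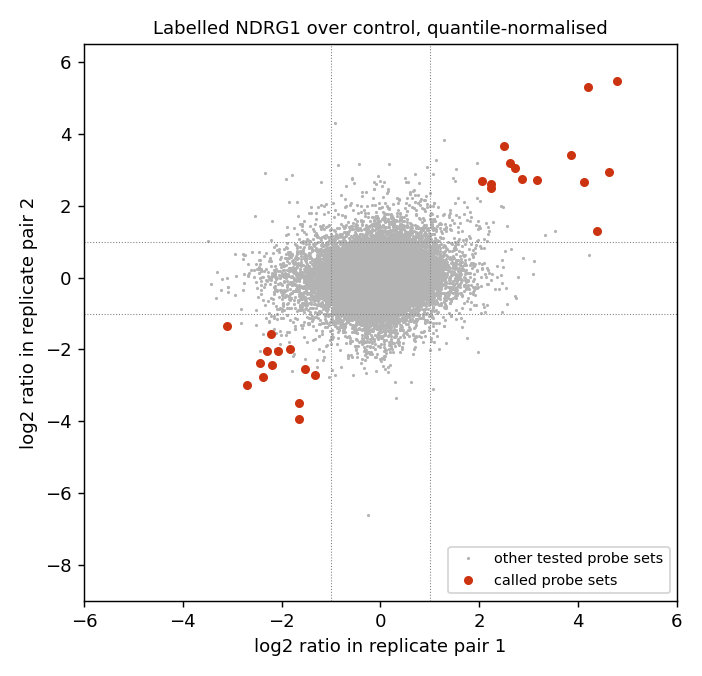
Log2 ratio of the array labelled NDRG1 transfected over the control after quantile normalization, for pair 1 (horizontal axis) and pair 2 (vertical axis), with each point a probe set. The 27 called probe sets lie outside the dotted lines, which mark a 2-fold change, in both pairs. Their selection on these same arrays favours this.

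Without a test, 1180 probe sets differed by at least 2-fold with no overlap between the groups, 178 higher and 1002 lower. After quantile normalization the count was 686, with 315 higher and 371 lower, so the share that was higher went from 15.1% to 45.9%. Non-overlap was found in 37.9% of tested probe sets as deposited and in 32.4% after quantile normalization, against the 33.3% that chance gives with 2 arrays per group. Within the pairs, 2460 probe sets differed by at least 2-fold in pair 1 and 2032 in pair 2. Of these, 250 changed in the same direction in both pairs and 105 in opposite directions, where 91.7 would share a direction if the pairs were independent.

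Genes of mitosis were lower as a group in the fit of all arrays, with a lower median in pair 2 than in pair 1. The difference between pairs rests on 1 array per group in each pair. After quantile normalization, the list median against the mean of the 4 arrays and relative to all genes was 0.565 in control 1 and 0.193 in control 2. It was 0.615 and -1.29 in the first and second arrays labelled NDRG1 transfected, so the low value lay in 1 extract. The median of the 36 tested genes was -0.85 relative to all genes, and camera gave an adjusted p of 5.49e-24 (adjusted p = 0.997 with an estimated correlation). After quantile normalization the median was 0.07 in pair 1 and -1.50 in pair 2, where all 36 lay below the median of all genes and 33 were at least 2-fold lower. Of the members, 0 were called over all genes and 23 were lower when adjusted over the list alone. The smallest p belonged to HMMR, a spindle-associated protein, at -1.59 relative to the median, then KIF2C at -1.30, KIF4A at -1.27 and the transcription factor FOXM1 at -1.35. The S phase and DNA replication genes were lower by less, with a median of -0.36 over 36 genes, an adjusted p of 2.65e-06 (adjusted p = 0.997 with an estimated correlation), and 0 members called. Their medians were -0.12 in pair 1 and -0.45 in pair 2, with PRIM1 at -1.04 and MCM2 at -0.85 in the fit of all arrays.

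The immediate early genes, genes induced within minutes of stimulation, were higher as a group, with a higher median in pair 2 than in pair 1, a difference that was not tested. The median of 22 genes was 0.53, with an adjusted p of 5.1e-08 (adjusted p = 0.997 with an estimated correlation), and 0 members were called. Their medians were 0.08 in pair 1 and 0.92 in pair 2, and FOS was -0.04 in pair 1 and 2.82 in pair 2, while FOSB was -0.91 and 4.30. Without the array labelled NDRG1 transfected of replicate 2, the median was 0.07 for mitosis, and this list passed in the opposite direction, with a median of -0.24 (adjusted p = 0.0334). Without the first such array the medians were -1.69 for mitosis and 1.41 for this list, which lay at 0.31 without control 1 and 0.85 without control 2.

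The collagens and extracellular matrix list was higher as a group, with members in both directions. It had a median of 0.55 over 23 genes (adjusted p = 0.000175, or adjusted p = 0.964 with an estimated correlation), with 1 member called, COL3A1. Adjusted over the list alone, 1 member was higher and 1, COL13A1 at -1.31, was lower. The medians were 0.34 and 0.36 in the pairs, where 9 and 7 of the 23 genes lay below the median of all genes. The median was 0.32 without control 1, 0.30 without the second array labelled NDRG1 transfected and 0.26 with a filter at the 75th percentile, and without the filter the adjusted p was 0.0527. The fibroblast markers shared the collagen genes, with a median of 0.67 over 5 genes (adjusted p = 0.000134, or adjusted p = 0.964 with an estimated correlation); COL1A1 was 0.68 and COL1A2 0.66 higher without being called, and DCN was 0.07. Without the first array labelled NDRG1 transfected the fibroblast median was 0.39 (adjusted p = 0.0164). Mesenchymal and EMT regulators had a median of 0.37 over 14 genes (adjusted p = 0.0188, or adjusted p = 0.997 with an estimated correlation), 0.13 in pair 1 and 0.70 in pair 2. TAGLN, an actin-binding protein, was 1.46, SNAI2 1.14, FSTL1 -0.24 and LOXL2 -0.57, none of them called. As deposited the rise of TAGLN lay in 1 array, with 262 and 281.608 in the controls against 240.7 and 1566.14. The groups overlapped for SNAI2 too, at 70.9546 in control 2 and 31.1 in the first array labelled NDRG1 transfected. The median was -0.01 without the second array labelled NDRG1 transfected, 0.60 without the first and 0.18 without control 1 (adjusted p = 0.327). The adjusted p was 0.12 with quantile normalization and 0.306 without the filter.

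Ductal markers had a median of 0.52 over 11 genes (adjusted p = 0.00505, or adjusted p = 0.997 with an estimated correlation), 0.56 in pair 1 and 0.15 in pair 2, with TFF1 at 1.32 and MUC1 at 1.11 and 0 members called. Without the first array labelled NDRG1 transfected the median was 0.30 (adjusted p = 0.271), and without the filter it was 0.29 (adjusted p = 0.068). Oxidative phosphorylation genes had a median of -0.15 over 35 genes (adjusted p = 0.0281, or adjusted p = 0.997 with an estimated correlation), 0.04 in pair 1 and -0.31 in pair 2. NDUFS3 at -0.56 and COX5A at -0.53 were among them, and the adjusted p was 0.172 with the replicate block, 0.0827 without control 1 and 0.724 without control 2, where the median was -0.01. Without the first array labelled NDRG1 transfected this median was -0.26, and without the filter it was -0.28. A filter at the 75th percentile gave -0.09 (adjusted p = 0.165). The adjusted p of this list was 0.0861 without the intensity trend and 0.205 over the mean of a gene's probe sets. For the other passing lists the block left the adjusted p between 2.07e-18 for mitosis and 0.0284 for the mesenchymal list. With 2 residual degrees of freedom the correlation within a list is poorly estimated, and none of the 8 lists passed with it.

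**Figure D3:**
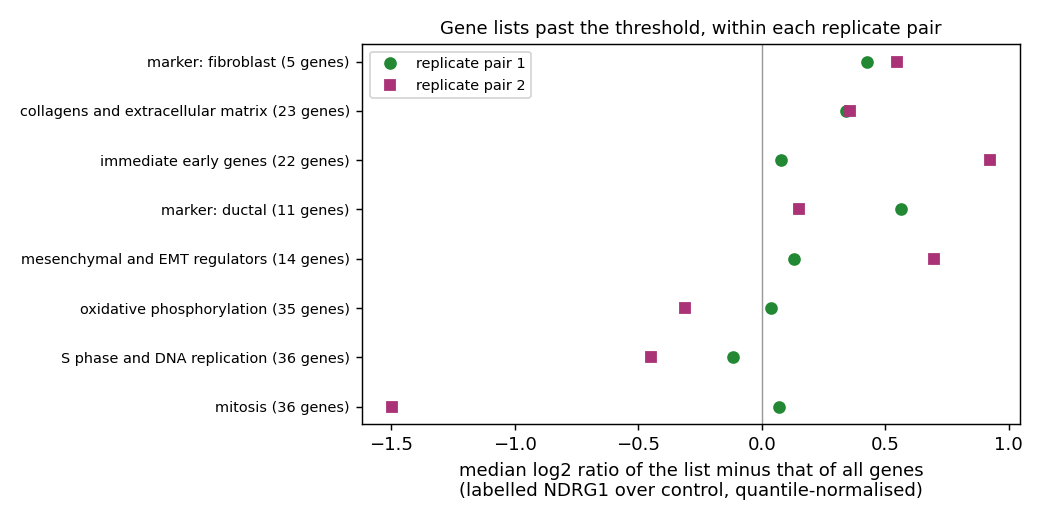
Median log2 ratio of each of the 8 gene lists past the threshold minus that of all genes, after quantile normalization, with circles for replicate pair 1 and squares for pair 2. Mitosis lies at 0.07 in pair 1 and -1.50 in pair 2, and the collagen list at 0.34 and 0.36.

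The other 33 tested lists did not pass in the main analysis, the lowest adjusted p being 0.104 for metallothioneins, and 8 of them held a called member. After quantile normalization camera passed metallothioneins (adjusted p = 0.00943) and MYC and NDRG1 upstream repressors (adjusted p = 0.0448) at the preset correlation. Adding the replicate block also passed the unfolded protein response and ATF4 targets (adjusted p = 0.0339). Genes linked to NDRG1 in earlier work had a median of 0.06 over 14 genes (adjusted p = 0.155), with NEDD4L higher and CTSC lower both over all genes and adjusted over the list alone. That list was compiled from recollection of earlier studies, may include genes chosen on these samples, and is not independent evidence. NEDD4L was also the called member of the NEDD4 family of ubiquitin ligases (11 genes, adjusted p = 0.182). FABP5 was called in fatty acid synthesis and storage (20 genes, adjusted p = 0.182), PMAIP1 in the p53 targets (20 genes, adjusted p = 0.931) and CTSC in the matrix proteases (25 genes, adjusted p = 0.899). TUBB2B was called in the cytoskeleton list (31 genes, adjusted p = 0.805) and ALDH1A3 in the drug metabolism list (16 genes, adjusted p = 0.359).

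The hypoxia response had a median of 0.13 over 28 genes (adjusted p = 0.912), the interferon response -0.07 over 24 genes (adjusted p = 0.432) and the iron list 0.18 over 19 genes (adjusted p = 0.595). ENO2 was -1.57 relative to the median, lower when adjusted over the hypoxia list alone and not called over all genes, as was IFITM3 at -1.70 in the interferon list. Of the markers of other cell types, neuronal genes had a median of 0.55 over 8 genes (adjusted p = 0.164), leukocyte genes 0.25 over 5 (adjusted p = 0.291) and islet genes -0.05 over 6 (adjusted p = 0.805). Endothelial and acinar markers, cancer-testis antigens and the NDRG family had 3 tested genes each and were not tested as lists. Their medians were -0.02, 0.21, 0.26 and -0.60. Median and mean differed in sign in 5 lists, among them cyclin-dependent kinase inhibitors, p53 targets, glycolysis and inflammatory genes.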

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

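The tests of explanations in this part were chosen only after the result was seen, except the comparison of the mitosis genes between the control arrays, and the counts of called probe sets with and without the replicate block were planned. Of the 62 control probe sets of the array maker, which the comparisons leave out, 4 had both arrays labelled NDRG1 transfected above both controls, where chance gives about 10.3. The ratio of the group means was 1.35 for AFFX-BioB-5_at, a spiked bacterial transcript, 1.98 for AFFX-M27830_3_at, a ribosomal RNA probe set, 1.97 for AFFX-TrpnX-5_at and 1.78 for AFFX-TrpnX-M_at, which read a bacterial transcript at signals of 1.4 to 15.7, where a ratio means little.

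The mitosis genes were lower in pair 2 and not in pair 1. A uniform factor between arrays cancels in a median relative to all genes, and a trend with intensity is argued against: the list's median in pair 2 came no closer to 0 than -1.50 under quantile and cyclic loess normalization, which moved no tested probe set there by over 0.281 relative to the median of all genes. A shift of the control 2 array is argued against too, as control 2 minus control 1 was -0.372 while the array labelled NDRG1 transfected of replicate 2 lay 1.49 below the lowest other array. For an effect of equal size in both pairs, the pair 1 median was 0.0719, against -0.75 for both pairs together. The gap passed 2 times both the SE of 0.231, from the members' estimated correlation, and the difference between controls. That SE is taken over the genes of 1 pair and does not measure the spread between extracts. An equal or a weaker shared effect therefore stays open with 1 array per group in each pair. Also open, and untested, is the state of that culture, since slower growth or a difference in density may lower mitosis genes in a single extract.

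Few differences were shared by the 2 pairs, whose log ratios correlated at 0.134 over all tested probe sets, across genes that are not independent. Noise of dim probe sets is argued against as the whole cause, since the correlation was 0.213 among 5462 probe sets, the brightest 10% of the whole array outside its controls. Labels swapped within a single pair are argued against by 250 probe sets that changed in the same direction in both pairs and 105 in opposite directions. A batch difference between the replicates, shown by their decimals and scaling, may account for part of it and was not tested separately.

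The NDRG1 signal was not higher in the arrays labelled NDRG1 transfected. Labels reversed in both pairs cannot be told apart from correct labels with a transgene that the probe set does not read, because NDRG1 differed by -0.0881 in pair 2 and by -1.15 in pair 1 after quantile normalization. No gene other than NDRG1 is known here to report the construct. The direction of every difference given for these arrays rests on the labels.

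The 4 arrays can be split into groups of 2 in 3 ways, too few for a share under 0.05. The real split called 27 probe sets, and the highest other split called 139, so 2 of the 3 gave at least as many. That other split is between the replicate numbers, which are the 2 batches, and points to a structure of the samples. With the replicate block 99 probe sets were called. These counts are for the values as deposited, and after quantile normalization each of the 3 splits called 0 without the block. The batch structure remained there. In the same limma fit 3104 probe sets had an unadjusted p under 0.05 in the split by replicate number. The real split had 909 and the remaining split 238.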

How the results depend on the processing

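Scaling to a common trimmed mean, the block combined with quantile normalization and the counts within a pair were chosen only after the data were seen; the other settings were planned. Against 27 called probe sets and 17 called genes, quantile, cyclic loess and trimmed-mean scaling each left 0 and 0, no filter 2 and 1, robust eBayes 82 and 40, and an unadjusted p under 0.05 with a 2-fold change 1250 and 605. Called genes numbered 11 without a pseudocount and 41 with the mean of a gene's probe sets. The replicate block gave 99 and 43, and the block with quantile normalization 40 and 26. The labels do not say that the numbers pair the extracts, and with 2 pairs the check is a hint: deviations of same-numbered arrays correlated at 0.37. Leaving out an array gave 4 to 1738 probe sets and 2 to 878 genes: 4 without control 1, 5 without control 2, and 912 and 1738 without the first and second arrays labelled NDRG1 transfected. The lone array of a group is then assumed to vary like the other group, and the controls lay closer together. The loss under quantile normalization went with a fall of the prior degrees of freedom from 33.3 to 4.38. Lists passing went from 8 to 5 without a filter, 13 with a filter at the 75th percentile, 0 with an estimated correlation, and 8 to 19 on leaving out an array, 19 and 15 without the first and second arrays labelled NDRG1 transfected. Probe sets at least 2-fold different went from 1180 to 579 with the median as pseudocount, 2534 without a filter, 686 with quantile normalization with or without the block, 754 with trimmed-mean scaling (468 higher and 286 lower), and 2460 and 2032 within pairs 1 and 2. The correlation of the arrays labelled NDRG1 transfected moved from 0.901 to 0.9263 without a filter, where dim probe sets enter. Leaving out the second array labelled NDRG1 transfected turned 3 list medians, which over the left-out arrays ranged from -1.69 to 0.07173 for mitosis, from -0.2361 to 1.406 for immediate early genes and from -0.008337 to 0.5959 for mesenchymal and EMT regulators, the other end in each case without the first array labelled NDRG1 transfected. Without the second such array the immediate early list passed in the opposite direction, at an adjusted p of 0.0334. NDRG1 stayed lower and past no threshold in every alternative, with or without the block. Over the alternatives the 17 genes gave 282 values, of which 169 kept direction and call, 113 lost the call and 0 turned. The 8 lists gave 134 values, of which 111 kept both, 20 lost the call and 3 turned. Unless a reason is given here, the cause was not tested. Signal over background was not assessed, as detection calls were not used.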

Other observations

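The genes of this part, apart from the regional test, were chosen only after their values were seen, and the regional test was set before its result was seen. With the replicate block and quantile normalization, 11 further genes passed an adjusted p of 0.05, 9 higher and 2 lower in the arrays labelled NDRG1 transfected. Among those higher, ALDH1A1, a retinaldehyde dehydrogenase, was 1.68 higher on the log2 scale (SE 0.17, adjusted p = 0.00133), with ALDH1A3 of the same family among the genes that fell. F2RL2, a thrombin receptor, was 1.90 higher (adjusted p = 0.00174) and RGS5, a regulator of G protein signalling, 1.92 higher (adjusted p = 0.0120). PRRG4 was 1.80, ST3GAL5 1.74, the vasodilator peptide ADM 1.67, MAP2 1.37 and APP 1.17 higher. The groups overlapped for ADM as deposited, at 757.561 in control 2 and 566.1 in the first array labelled NDRG1 transfected. The 2 lower genes were PHLDB2, at -1.68, and PLAU, the urokinase protease, at -1.62. TXNIP was 1.01 higher in pair 1 and 1.99 in pair 2. Every gene named here went the same way in both pairs, which their selection on these same arrays favours. This combination of settings was added after the data were seen. The fit with the block has 1 residual degree of freedom, so its SE relies on the spread shared across probe sets. With the block alone PHLDB2 passed (adjusted p = 0.0359) and the others did not, the lowest adjusted p among them being 0.0629 for PLAU. With quantile normalization alone none of them passed, the lowest adjusted p being 0.378 for ALDH1A1, and without either none passed.

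Called probe sets of LAPTM5 and PAGR1 were not the brightest of their gene and so were not counted among the 17 genes.

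Neighbouring genes differed together between arrays. A candidate explanation is regional gains or losses of DNA between the cultures, since tumour lines drift. The correlation of a gene's log ratio with the median of its 5 neighbours on either side, over 12091 genes in the order of the RefSeq table, was 0.11 in pair 1 and 0.107 in pair 2. The highest of 1000 shuffles of the gene order gave 0.0368 and 0.0406. It was 0.15 between the 2 controls and 0.0629 between the 2 arrays labelled NDRG1 transfected, above all 1000 shuffles in each case. The bound of 0.1 set before the test was passed narrowly. The pattern was thus also found between arrays of the same transfection, and was strongest between the controls. That comparison crosses the 2 batches, so it cannot settle whether the pattern within the pairs goes with the transfection. Whether the same regions differed in both pairs was not tested. Shared regulation of neighbouring genes would give the same value and was not separated from it.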
